A study of Mus musculus with 2 samples.

How the data were processed

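Genomic DNA from manually dissected V/SVZ and CP of ICR mouse embryos at embryonic day 16 was enriched for methylated fragments with the Methylated DNA Enrichment Kit and made into multiplexed libraries with Illumina's ChIP-Seq preparation kit, per the labels' protocols. There was 1 library per tissue. CASAVA 1.8 and Bowtie (version not given in the sources used here) and the genome build mm9 are named in the submitters' processing notes. The column names of the peak tables are those of the peak caller MACS, per the file headers, and its version and settings are not given in the sources used here. Peaks were called per library: each tissue against a control, whose nature is not stated in the sources used here, and each tissue directly against the other. The 4 deposited tables hold a line for each peak and each RefSeq transcript within 10 kb.

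In the deposited tables the tags of a peak are a count of that library's reads, not normalized, per the file headers. The significance of a peak is a score computed by the authors, the negative log10 of the peak caller's p times 10. The fold is the authors' ratio of the peak to its local expectation, and it describes and ranks peaks within a list only. The false discovery rate is a percent given by the authors, 0 for every control peak. It was 0 to 90.0 for V/SVZ over CP and 100 for every CP over V/SVZ peak, so that the CP over V/SVZ list has no support from that rate. Peak length and distance to the transcript are in bp, per the file headers. Coordinates are 1-based in mm9, and the end minus the start plus 1 equals the deposited length for 100% of peaks.

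The V/SVZ and CP control tables each hold 65535 lines in order of decreasing fold. Peak numbers reach 58582 and 69397, so 6299 and 15993 numbered peaks are not in the tables used here, and 89.2% and 77.0% are. Control peaks are thus listed only down to a fold of 11.48 in V/SVZ and 14.71 in CP, and a direct peak in neither control list can lie in an unlisted region. The largest fold is 50 in both tables, reached by 3175 and 2227 peaks. The direct tables hold every numbered peak. The median peak over control had 11 tags in V/SVZ and 17 in CP, in lists that end at different folds, and at such counts a ratio between the libraries carries a wide exact interval. The library totals are not given in the sources used here, so no ratio was scaled by depth, and the median ratio at shared autosomal peaks stands beside the others instead.

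The design, the alternatives and the gene lists were fixed before the data were examined. Groups were taken from the tissue labels. With 1 library per tissue no p is given. Gene lists and classes of peaks were placed among random lists and sets, which shows whether they stand out within these libraries and not whether the tissues differ between animals. Overlap was counted from 1 bp, with 100 circular shifts of the other list along each chromosome for the overlap that random placement gives. Promoter peaks were those whose annotation placed them over the 5' end or the whole of a transcript, or upstream within 1 kb. The deposited distance is 0 for any peak inside a transcript, so a peak inside a gene close to its 5' end is not counted as a promoter peak. Upstream and downstream were on opposite sides of the gene in 98.9% of 1188 V/SVZ genes and 99.3% of 1144 CP genes that had peaks upstream, inside and downstream. Shares carry Wilson 95% intervals and ratios of 2 tag counts exact binomial 95% intervals. Both cover counting error only, since 1 library per tissue gives no replicate error. The exact intervals also treat reads as independent molecules. Reads without molecular identifiers are not, so these intervals can be too narrow.

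A gene list was described by the number of its members with at least 1 direct peak, among the 13194 genes with a control peak in either tissue, and by the percentile of that number among 10000 random lists. Random lists were matched on the number of control peaks per gene in 8 bins, because long genes hold more peaks (10 bins were planned, and ties joined some). Of 28 lists, 27 had members in the background, and 54.6% of background genes carried a V/SVZ over CP peak and 57.0% a CP over V/SVZ peak. The 2.5th and 97.5th percentiles bound the range called random. Lists were called by percentile, in which random lists of equal count were split evenly. A count equal to an end of the range can thus be called outside it. Gene symbols and IDs are those in the files. Of 13253 gene IDs, 13198 (99.6%) were in a RefSeq gene table of assembly GRCm38.p6, of which no coordinates were used.

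Named genes followed a fixed rule for each direct list: the genes of the 12 most significant peaks within a control peak of the same tissue; up to 12 list members with a promoter peak, by significance; the 5 genes with the most peaks; and up to 4 members of each list described, by significance. Further members with promoter peaks were named after their values were seen, and the genes that escape X inactivation were chosen after the X chromosome result but before their own peaks were counted. Some genes that the rule selects are withheld and not reported here. Where both tissues had a control peak at the position of a direct peak, the tags of both are given.

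Tags per library were compared at control peaks that overlapped exactly 1 peak of the other tissue. Medians carry bootstrap intervals over peaks from 2000 draws, and percentiles come from 10000 random sets of autosomal pairs matched on mean tags in 10 bins. This comparison was added after the data were examined. The alternatives tried were peaks above the median significance of a list, folds above the median, autosomes only, merging within 1 kb, overlap of 50% of a peak or of both peaks, a promoter distance of 5 kb, peaks in the gene body or 5 kb of it, unmatched random lists, and direct peaks within control peaks. Added after the data were examined were the same lowest fold in both control lists, false discovery rates of at most 50% and 5%, peaks over the 5' end alone, promoter peaks alone and autosomal genes alone for the gene lists, and tags per bp, a mean of at least 20 tags and reciprocal overlap for the tag ratio.

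The functions were tested on simulated data. For the overlaps between peak lists, 20000 simulated peaks with a planted overlap of 30% gave 30%. For the gene lists, simulated with 12000 genes, 1.33% of null lists and 1.33% of lists of peak-rich genes exceeded the upper bound, and 72.3% of lists in which carriers were drawn 3 times as often did. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.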

Results

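DNA methylation was profiled in 2 layers of the cerebral wall of ICR mouse embryos at embryonic day 16. The V/SVZ includes the ventricular zone, where neuronal progenitors are abundant. The cortical plate (CP) is populated by neurons that are differentiating. Methylated DNA was captured with a methyl-binding-domain kit and sequenced (MBD-seq), so that regions dense in methylated CpG sites gave many tags (aligned sequence reads). The data comprised 1 library from each tissue, and there was therefore no replicate error for any difference given here. The V/SVZ library had 1000061 tags in 52283 listed peaks over control, with a mean of 19.13 tags per peak over 22.1 Mb. The CP library had 1710134 tags in 53404 listed peaks, with a mean of 32.0 tags over 24.3 Mb. The total number of sequenced tags per library was not given in the sources used here. Intervals around shares and ratios cover counting error only. The tags given for a gene in V/SVZ and CP were counted over each library's own peak. These peaks can differ in length, and the ratios are not corrected for it.

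The comparison of each tissue with the control asked where methylated DNA was enriched. Peaks were assigned to 11914 genes in V/SVZ and to 12354 genes in CP. In both tissues most listed peaks lay away from gene promoters: 1.28% of the V/SVZ peaks and 1.59% of the CP peaks overlapped the 5' end of a gene or lay within 1 kb upstream of it. The X chromosome differed from the autosomes in this respect. On X, 126 of 1490 V/SVZ peaks (8.46%, Wilson 95% interval 7.15 to 9.98%) and 269 of 2294 CP peaks (11.7%, 10.5 to 13.1%) were promoter peaks, against 1.07% and 1.13% on the autosomes. Peaks inside a gene made up 44.0% of the V/SVZ list and 39.4% of the CP list. The median peak was 355 bp long with 11 tags in V/SVZ and 378 bp long with 17 tags in CP. The fold of each peak is the authors' own value, given by their peak caller for that library alone, and ranged from 11.48 to 50 in V/SVZ and from 14.71 to 50 in CP. Both lists end at these lowest folds, and peaks of lower fold were not analysed here.

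The tissues shared most of their listed enriched regions. Of the V/SVZ control peaks, 33733 (64.5%, Wilson 64.1 to 64.9%) overlapped a CP control peak by at least 1 bp, and 33575 CP control peaks (62.9%, 62.5 to 63.3%) overlapped a V/SVZ control peak. When the other list was shifted at random along each chromosome, the mean overlap over 100 shifts was 1.83% and 1.77%. Promoters of germline genes, which somatic cells hold methylated, were among the shared regions. The promoter of Sycp1, a component of the meiotic synaptonemal complex, held 107 tags in V/SVZ and 401 in CP (chromosome 3, 102739192 to 102740243, mm9), and the promoter of Ddx4, a germ cell RNA helicase, held 33 and 136 (chromosome 13, 113442002 to 113442808). Sharing depended on the fold: 48.1% of the V/SVZ peaks in the lowest tercile by fold and 79.8% of those in the highest overlapped a CP peak, and the corresponding CP values were 53.1% and 75.4%. Because the lists stop at a lowest fold, partners below that fold in the other tissue are not seen, which lowers the shares. Peaks of low fold in the counted list are missing too, which can raise them, since such peaks were shared less. The shares thus hold for the listed peaks only.

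The direct comparison of V/SVZ with CP asked which regions were more enriched in the progenitor layer. The list held 21914 peaks over 7.78 Mb, assigned to 7229 genes. Among genes of cortical neurons, Cux2, a transcription factor of upper layer neurons, had 29 peaks, Cdh13, a cadherin, had 20, and Bcl11b, a transcription factor of deep layer corticospinal neurons, had 8. The gene with the most peaks was Camta1, a calmodulin-binding transcription activator, with 35, followed by Cux2, by the protein kinase C gene Prkce with 23, and by Cdh13 and the sialyltransferase gene St6galnac3 with 20 each. Camta1 also had 13 peaks in the opposite list, and Cux2, Cdh13, St6galnac3 and Prkce had 4, 3, 3 and 2 there. Bcl11b had 1 there, of 1577 CP tags, whereas its most significant V/SVZ over CP peak held 21. Only 154 peaks (0.703%, Wilson 0.600 to 0.822%) were promoter peaks, and 47.3% lay inside a gene.

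The peaks with the highest significance given by the authors, among those within a V/SVZ control peak, lay mostly inside genes. The first was in Scfd2 (gene ID 212986, chromosome 5, 74704066 to 74705199), with 317 tags in V/SVZ and 13 in CP, a CP to V/SVZ ratio of 0.0410 (exact 95% interval 0.0216 to 0.0711). Ncoa2, a nuclear receptor coactivator (gene ID 17978, chromosome 1, 13308053 to 13309044), followed with 213 tags against 27, and the helicase gene Fbxo18 (gene ID 50755, chromosome 2, 11665830 to 11666740) with 292 against 76. For comparison, the median ratio at all autosomal peaks shared by the tissues was 1.81; how much of it comes from depth is not known. Peaks in Ddx58 (122 tags), Il34 (123), Prkce (58), Zp2 (52), Igsf21 (46) and Elf2 (44) overlapped no listed CP control peak. Ccdc3 (328 against 158 tags), Dock9 (390 against 259) and a peak upstream of Zdhhc2 (756 against 647) were enriched in both tissues. Their CP to V/SVZ ratios were 0.482, 0.664 and 0.856. Igsf21 (5), Ncoa2 and Dock9 (4 each), Ddx58 and Il34 (2 each) and Elf2 (1) also had peaks in the opposite list. Members of the gene lists with a promoter peak included Crym, a thyroid hormone binding protein of deep layer neurons (11 tags, 71 bp upstream), and the imprinted gene Peg3 (20 tags, 490 bp upstream). The Peg3 peak lay in a CP control peak of 262 tags and in no listed V/SVZ control peak, and Peg3 also had 3 peaks in the opposite list. The authors' false discovery rate was at most 5% for 16 peaks of this list and at most 50% for 6022, with a median of 67.6%.

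Neuronal layer genes stood at the upper end of the random lists in the V/SVZ over CP comparison. All 9 upper layer genes that had a control peak carried such a peak, against a mean of 6.38 in random lists matched on the number of control peaks (percentile 98.9). Examples beside Cux2 and Cdh13 were Epha3, with 69 tags in V/SVZ and 44 in CP, and Mef2c, with 7 tags in V/SVZ and no listed CP control peak. Of 12 deep layer genes, 10 carried a peak, against a mean of 6.71 (percentile 98.5), among them Crym, Bcl11b, Ldb2 (9 tags) and Foxp2 (14 tags). The count of 10 equals the upper end of the central 95% of random lists (4 to 10). Only the percentile lay above it. Of 13 radial glia and progenitor genes, 9 carried a peak (percentile 97.46, just inside the central 95% of random lists), including Notch2 (27 tags against 8), Tnc (13) and the glutamate transporter gene Slc1a3 (12 against 7). In the opposite list Tnc had a larger peak (104 tags in V/SVZ and 300 in CP, ratio 2.88, 2.30 to 3.64) and Notch2 a peak of 58 CP tags, and Ldb2 and Foxp2 had 1 peak each. The median ratio at shared autosomal peaks was 1.81. Intermediate progenitor genes (6 of 8, percentile 93.1; Dll1, 33 tags) and postmitotic neuron genes (11 of 13, percentile 95.9; Dlg4, 29 tags) lay within the random range. With 27 lists, about 0.675 would lie above the range by chance. The upper layer list stayed above the range in 2 of 6 alternatives: it fell back with direct peaks within a V/SVZ control peak (percentile 94.6), with the more significant peaks (96.0), with peaks in the gene body or 5 kb of it (97.48) and with promoter peaks alone (42.7). The deep layer list stayed above it in 5, falling to 92.3 with promoter peaks alone. With unmatched random lists and on autosomes its count again only equalled the upper end of the range. The same held for the upper layer list on autosomes. With promoter peaks alone random lists had a mean of only 0.156 carriers for the upper layer list and 0.155 for the deep layer list. That alternative thus says little about these calls. The radial glia list rose above the range with the more significant peaks (98.7), and the postmitotic neuron list with peaks within a V/SVZ control peak (98.2) and with unmatched random lists (98.3).

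Other lists stood low in this comparison. None of the 9 erythroid genes with a control peak carried a V/SVZ over CP peak (percentile 0.750). Of 24 germline genes, 8 carried one (percentile 0.790), among them the Tudor domain gene Tdrd1 (43 tags) and the Piwi gene Piwil1 (35). Of 27 genes of the TGF-beta, BMP and FGF pathways, 10 did (percentile 2.38), and Bmp7 had the most significant of these peaks, with 41 tags. The count of 10 equals the lower end of the random range (10 to 19), so only its percentile lay below. In the opposite list Bmp7 had 4 peaks, Tdrd1 3, Piwil1 2, and Pcdhga1 and Pcdhga2 7 each. Of the 56 clustered protocadherins, 22 did (percentile below all 10000 random lists), but the count came from 3 distinct peaks shared by overlapping transcripts such as Pcdhga1 and Pcdhga2. With promoter peaks alone no list can lie below the range, because many random lists then also carry 0 peaks. That alternative tells nothing about these calls. In the other 5 the protocadherins stayed below. The TGF-beta, BMP and FGF list did so on autosomes alone, with percentiles of 24.0 with peaks in the gene body or 5 kb of it, 5.75 with the more significant peaks, 7.54 within control peaks and 3.44 with unmatched random lists. The germline list was lost with the more significant peaks (15.4) and within control peaks (3.79). Erythroid genes carried 0 peaks throughout, but with peaks in the body or 5 kb of it (4.11) and with the more significant peaks (6.73) that lay within the range, which then starts at 0. The range also starts at 0 within control peaks (1.52) and on autosomes (1.565). In these only the percentile, and not the count, lay below it.

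The reverse comparison asked which regions were more enriched in CP than in V/SVZ, and the X chromosome was over-represented in it. X carried 1378 of these peaks (6.996% of the list, against 4.30% of the CP control peaks) and 227 in the opposite direction, 6.07 times as many (exact 95% interval 5.27 to 7.02). On individual autosomes the same ratio ranged from 0.717 on chromosome 5 to 1.15 on chromosome 7. Per 100 control peaks of the same tissue, X held 60.1 CP over V/SVZ peaks and 15.2 V/SVZ over CP peaks, and no autosome exceeded 39.7 or fell below 35.8, respectively. Many of the X peaks were at promoters: 265 of 1378 (19.2%, Wilson 17.2 to 21.4%), against 1 of 227 in the opposite direction. Over all chromosomes 517 of 19696 peaks (2.62%, 2.41 to 2.86%) were promoter peaks, and on the autosomes 251 of 18249 (1.38%, 1.22 to 1.55%), against 153 of 21643 (0.707%, 0.604 to 0.828%) in the V/SVZ over CP list. Leaving out the sex chromosomes thus lowered the promoter share from 2.62% to 1.38%.

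**Figure D1:**
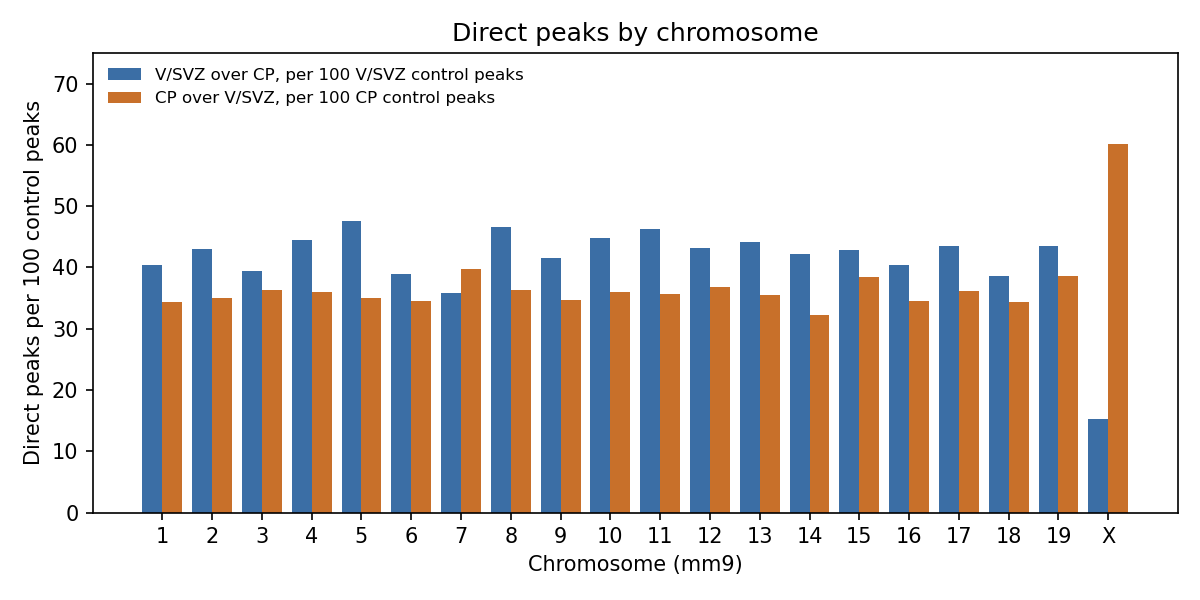
Bars give the number of direct peaks per 100 control peaks of the same tissue (vertical axis) on each chromosome of mm9 (horizontal axis), for V/SVZ over CP and for CP over V/SVZ, with 1 library per tissue. On X the values were 15.2 and 60.1, outside the ranges of the autosomes.

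Among the 12 genes with the most significant CP over V/SVZ peaks within a CP control peak, 10 were on X. The promoter of Msl3, a member of a chromatin complex (gene ID 17692, X, 165111234 to 165112504), held 8 tags in V/SVZ and 171 in CP, a ratio of 21.4 (exact 10.6 to 50.3). The promoters of the phosphatase gene Mtmr1 (75 tags), Morf4l2 (106), Prkx (114), B630019K06Rik (140) and the mitochondrial flavoprotein gene Aifm1 (55) held CP tags and overlapped no listed V/SVZ control peak. The promoter of Alg13, a gene of protein glycosylation, held 45 tags in V/SVZ and 275 in CP (ratio 6.11, 4.45 to 8.57). Zfp92 (14 against 176 tags) had a peak inside the gene. A peak downstream of Utp14a held 99 CP tags, and a peak 4855 bp upstream of Foxp3 held 30 tags in V/SVZ and 208 in CP. The V/SVZ tags of Zfp92 and Foxp3 were each summed over 2 peaks. The 2 autosomal genes were Irs2, an insulin receptor substrate (30 against 281 tags, ratio 9.37, 6.42 to 14.1; chromosome 8, 11004406 to 11006379), and Chrm3, a muscarinic acetylcholine receptor (43 tags in CP and no listed V/SVZ control peak at chromosome 13, 10202089 to 10202446; the gene also had 2 V/SVZ over CP peaks elsewhere).

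Of the list members, X genes and germline genes led the promoter peaks in this direction. The synaptic vesicle gene Syn1 (17 tags in V/SVZ, 157 in CP, ratio 9.24, 5.59 to 16.3), the purine salvage gene Hprt1 (7 and 104, ratio 14.9, 6.96 to 37.9), Fgf13 (22 and 153) and Zbtb33, which encodes a methyl-CpG binding protein (39 CP tags), are on X, as is the germline gene Taf7l, with 680 tags in its direct peak. V/SVZ over CP peaks were also assigned to Utp14a, Tdrd1, Plagl1, Mov10l1, Igf2r and Peg10 (2 each), Syn1, Hprt1, Sycp1 and Mest (1 each) and Vmn2r99 (4). On the autosomes the promoters of Tdrd1 (44 and 236 tags), Sycp1 (107 and 401), Mov10l1 (62 and 250), Sycp2 (76 and 283), Ddx4 (33 and 136) and Piwil2 (9 and 59), all germline genes, were in this list. The promoter of the imprinted zinc finger gene Plagl1 was as well (67 and 269 tags, ratio 4.01, 3.06 to 5.33; chromosome 10, 12810175 to 12811167). The ratio of Sycp1 was 3.75 (3.02 to 4.68) and that of Piwil2 6.56, beside the median of 1.81 at shared autosomal peaks. The genes with the most peaks were Camta1, Pcdha1 and Vmn2r99, a vomeronasal receptor gene, with 13 each, and Pcdha3 and Pcdha4 with 12. The Pcdha transcripts overlap and share peaks, among them their most significant (chromosome 18, 37250015 to 37250538), so these are not separate counts. The authors' false discovery rate was 100% for every peak of this list.

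3 gene lists stood above the random range in the CP over V/SVZ comparison, against 0.675 by chance. Of 24 germline genes, 21 carried such a peak, against a mean of 13.7 in random lists (percentile 99.98, with 3 of the 21 on X), and 16 of the 33 genes listed had it at the promoter, including Dazl, Brdt, Tex14 and Hormad1. Of 40 imprinted genes, 30 carried a peak, against a mean of 21.2 (percentile 99.8), and 13 had it at the promoter, from 11 distinct peaks, including Gnas, Igf2r, Mest, Peg10 and Peg12. In the body of Grb10, an imprinted growth factor receptor adaptor, a peak held 176 tags in V/SVZ and 713 in CP (ratio 4.05, 3.43 to 4.81). Of the 56 clustered protocadherins, cell adhesion genes of neurons, 52 carried a peak, against a mean of 38.4 in random lists, none of which reached that number. These came from 32 distinct peaks, so that members were not independent. An example was a peak within Pcdhb7 with 76 tags in V/SVZ and 246 in CP. The imprinted and germline lists stayed above the range in all 6 alternatives, and the protocadherins in 5, falling to percentile 83.9 with promoter peaks alone. At first no list stood below the range, but with peaks within CP control peaks alone the postmitotic neuron list did (3 of 13 genes, percentile 0.880).

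**Figure D2:**
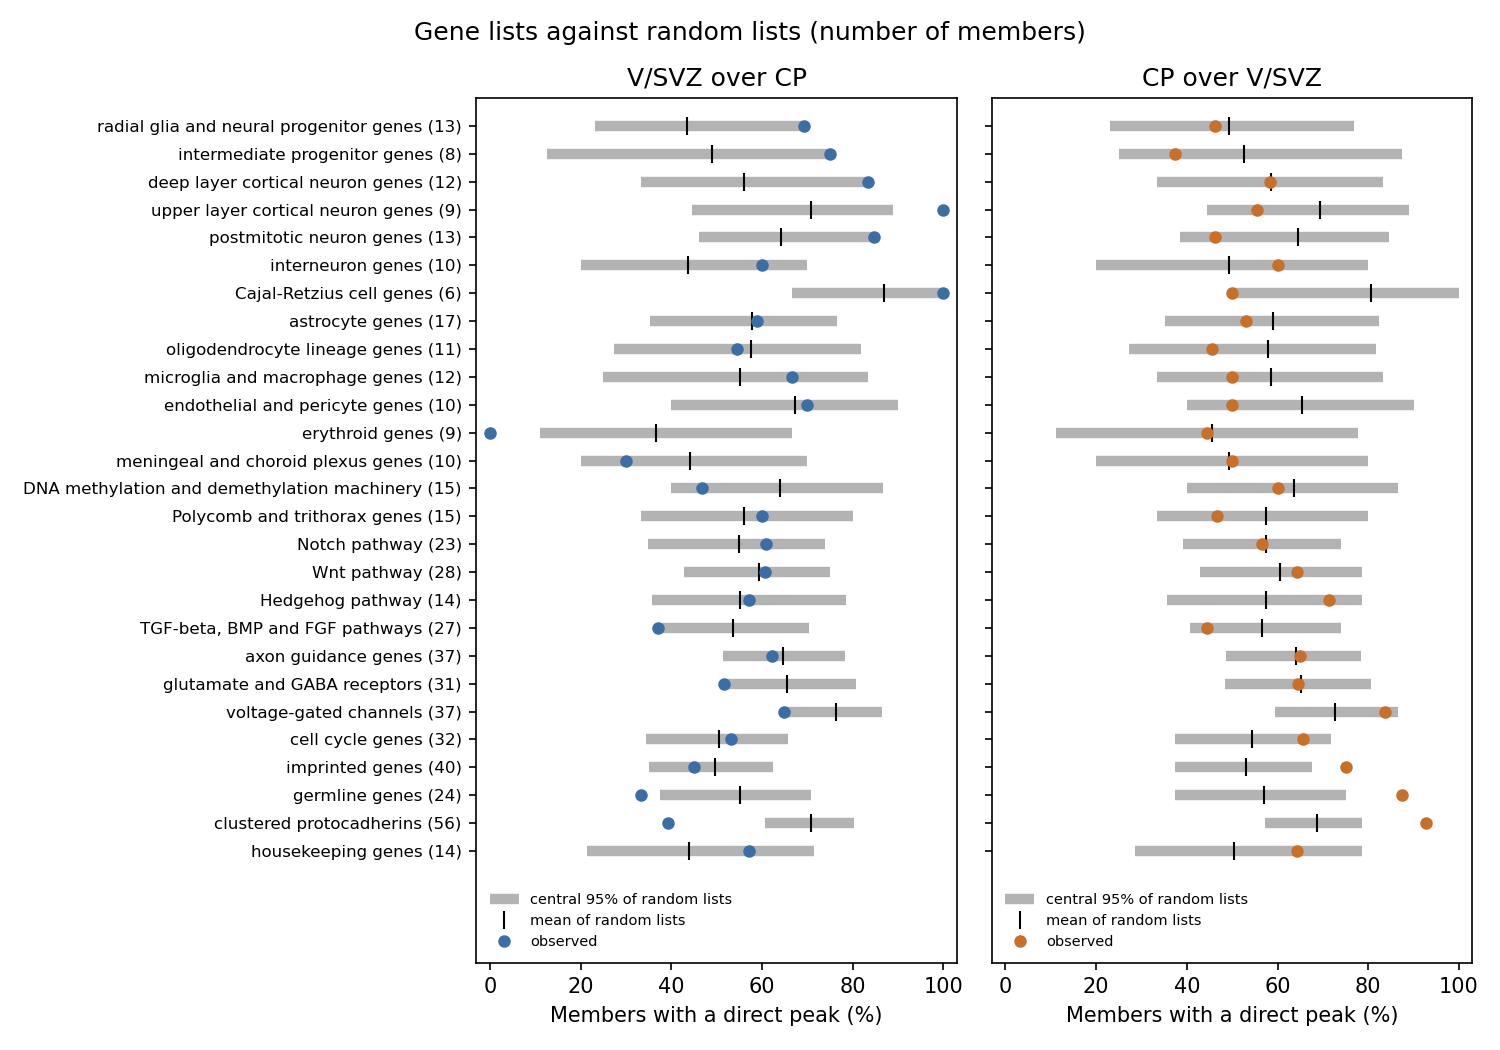
Points give the share of each list's members with a direct peak (horizontal axis, percent) for V/SVZ over CP on the left and CP over V/SVZ on the right, grey bars the central 95% of 10000 random lists and ticks their mean; the number of members follows each name. In the CP over V/SVZ panel the imprinted (30 of 40), germline (21 of 24) and protocadherin (52 of 56) lists lie to the right of the grey bars.

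Direct peaks were set beside the control peaks of each tissue. This could not separate gain in the tissue named first from loss in the other. Control peaks of low fold are unlisted, and direct peaks within a control peak of their own tissue repeat that peak. Of the V/SVZ over CP peaks, 85.0% lay in a V/SVZ control peak and 26.0% in a CP control peak, and 14.8% in neither. Of the CP over V/SVZ peaks, 77.4% lay in a CP control peak, 28.2% in a V/SVZ control peak and 21.2% in neither. Every direct peak within a control peak of its own tissue had the same coordinates as that control peak, as those of Scfd2 and Msl3 had. The promoter peak of Taf7l was among the 287 (1.46%) CP over V/SVZ peaks that lay in a listed V/SVZ control peak and in no listed CP one. A CP control peak below the lowest listed fold can lie at such positions. The direct lists overlapped each other at 36 peaks, 0.164% of the V/SVZ over CP list, against a mean of 0.634% in shifted lists. They are opposite calls on the same libraries, so a low overlap is built in and tells nothing about the tissues.

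Tags were then compared at 33328 peaks that paired uniquely between the control lists, a measure added after the data were examined. The CP library held more tags at the median autosomal pair, with a log2 ratio of CP to V/SVZ tags of 0.86 over 32097 pairs. X promoters stood highest, with a median of 2.43 over 119 pairs (bootstrap 95% interval over peaks 2.21 to 2.61), and X peaks outside promoters had a median of 1.39 over 1035 pairs (1.32 to 1.45). Promoters of germline genes on the autosomes had a median of 1.90 over 18 pairs (1.49 to 2.00), promoters of imprinted genes 1.75 over 8 (1.32 to 2.15), and the other autosomal promoters 1.08 over 412 (0.97 to 1.15). Peaks on Y and on unplaced Y sequence, most of them on the latter, had a median of 0.58 over 27 pairs, with an interval of 0.22 to 1.00 that includes the autosomal median. Peak lengths differed between libraries: in tags per bp the excess of X promoters over the autosomal median fell from 1.57 to 0.87.

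**Figure D3:**
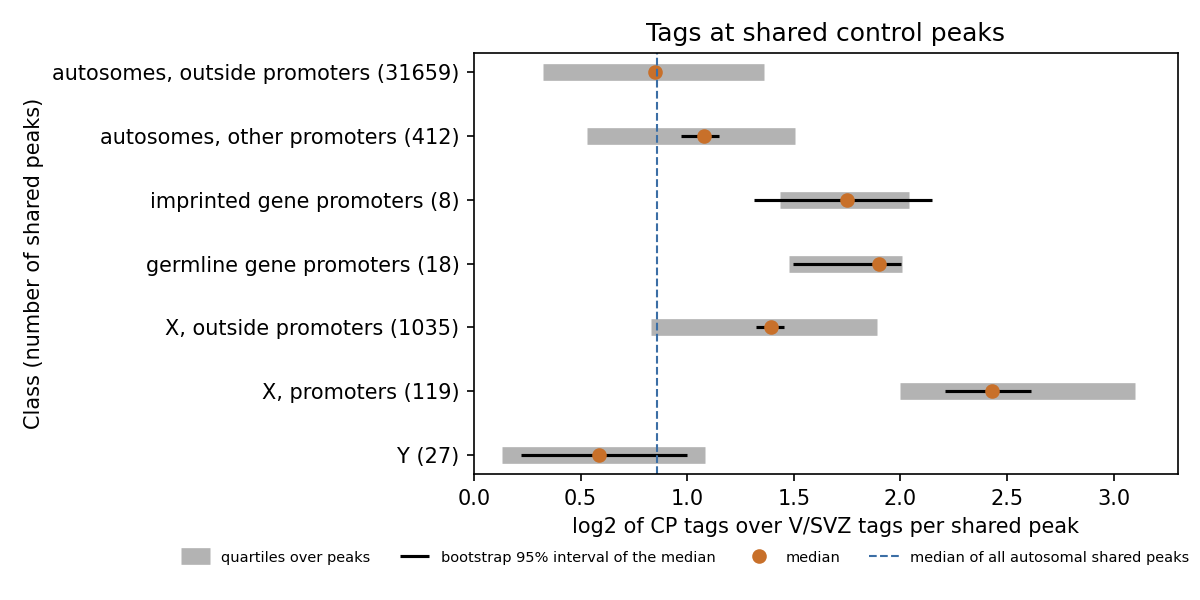
Points give the median log2 ratio of CP to V/SVZ tags per shared control peak (horizontal axis) for classes of peaks (vertical axis, with the number of peaks), grey bars the quartiles and black lines the bootstrap 95% interval of the median. The dashed line marks the median of all autosomal shared peaks, 0.86, and X promoters lie at 2.43.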

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

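Of 54 percentiles of gene lists, each set against 6 alternatives, 295 of 324 values stayed on the same side of the random range, 29 moved and 0 reversed. Most of the lists lay inside the range at first. Of those outside it, the imprinted and germline lists stayed above it for CP over V/SVZ in all 6, and the protocadherins in 5. For V/SVZ over CP, deep layer genes and protocadherins kept their side in 5. Erythroid and germline genes did so in 3, upper layer genes in 2 and TGF-beta, BMP and FGF genes in 1. The tag ratios kept 11 of 15 values and the counts of named peaks 7 of 8. Of 76 alternatives for the other results, 33 stayed and 43 moved. Only a change in size was scored for these, so a reversal could not be recorded. All that moved follow. Some that stayed could not move: direct peaks have the coordinates of their control peaks, so stricter overlap changes nothing, and the CP control list already ends at the shared lowest fold. With promoter peaks alone no gene list can fall below the range, because many random lists then also carry 0 peaks. Where no reason is given, the cause was not tested.

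Peaks above the median significance number, by construction, 26186 for V/SVZ and 26877 for CP over control, 10957 for V/SVZ over CP and 9879 for CP over V/SVZ. Above the median fold there are 26032, 25389, 10543 and 9848. A false discovery rate of at most 50% left 6022 V/SVZ over CP peaks and 0 CP over V/SVZ peaks, and at most 5% left 16 and 0; these rates, chosen after seeing the data, end the CP over V/SVZ list.

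The V/SVZ control peaks shared with CP were 78.6% at higher significance, 73.0% at higher fold, 64.1% on autosomes, 63.3% when 50% of the peak had to overlap and 59.3% when 50% of both had to. For CP control peaks the values were 83.5%, 73.8%, 63.4%, 59.1% and 58.1%. With the same lowest fold in both lists, chosen after seeing the data, they were 67.9% and 60.1%, and 78.3% of V/SVZ over CP peaks lay in a V/SVZ control peak. That share was 91.5% at higher significance and 88.5% at higher fold; for CP over V/SVZ in CP it was 83.5% and 78.7%.

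Promoter shares within 5 kb were 3.87% for V/SVZ over CP and 6.98% for CP over V/SVZ, since more peaks count by construction. Over the 5' end alone, chosen after seeing the data, they were 0.246% and 2.11%. For CP over V/SVZ the share was 3.66% at higher significance and 1.38% on autosomes.

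On X the ratio of CP over V/SVZ to V/SVZ over CP peaks was 8.15 at higher significance, 7.30 at higher fold and 5.26 within control peaks, the last chosen after seeing the data. The X promoter share was 23.3% and 22.4% at higher significance and fold. The number of gene lists above the random range for V/SVZ over CP, 2 at first, was 1 with peaks in the body or 5 kb of it, 4 with unmatched random lists and 0 with promoter peaks alone.

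No paired analysis was possible because each tissue has only replicate 1, whose litter is not stated in the sources used here. Leaving out replicates could not be done with 1 library per tissue.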

Other observations

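Genes of several other groups carried direct peaks in numbers within the random range. For V/SVZ over CP these were interneuron (6 of 10), Cajal-Retzius (6 of 6), astrocyte (10 of 17), oligodendrocyte (6 of 11), microglia (8 of 12), endothelial (7 of 10) and meningeal and choroid plexus genes (3 of 10). They also were DNA methylation genes (7 of 15; Dnmt3a, 40 tags in V/SVZ and 13 in CP), Polycomb and trithorax genes (9 of 15), Notch (14 of 23; Notch2, 27 and 8), Wnt (17 of 28) and Hedgehog genes (8 of 14; Gli2, 35 and 14). Axon guidance genes (23 of 37; Robo1, 141 and 82), glutamate and GABA receptors (16 of 31; Grm5, 46 and 20), voltage-gated channels (24 of 37), cell cycle (17 of 32), imprinted (18 of 40) and housekeeping genes (8 of 14) lay in the range as well. In the opposite list Gli2 had 3 peaks, Dnmt3a 2, and Robo1, Grm5 and Notch2 1 each. Alternatives took some of these out of it: voltage-gated channels fell below with the more significant peaks (percentile 2.36) and on autosomes (2.41), receptors fell below within control peaks (0.705), and Cajal-Retzius genes rose above with unmatched random lists (98.7).

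For CP over V/SVZ the same held for radial glia (6 of 13), intermediate progenitor (3 of 8), deep layer (7 of 12), upper layer (5 of 9), postmitotic neuron (6 of 13), interneuron (6 of 10), Cajal-Retzius (3 of 6), astrocyte (9 of 17), oligodendrocyte (5 of 11), microglia (6 of 12), endothelial (5 of 10), erythroid (4 of 9) and meningeal genes (5 of 10). It held for DNA methylation (9 of 15), Polycomb (7 of 15), Notch (13 of 23; Maml3, 23 tags in V/SVZ and 114 in CP), Wnt (18 of 28), Hedgehog (10 of 14) and TGF-beta, BMP and FGF genes (12 of 27). Axon guidance (24 of 37), receptor (20 of 31), channel (31 of 37; Cacna1g, 16 and 120), cell cycle (21 of 32) and housekeeping genes (9 of 14) completed the group. Maml3 and Cacna1g also had 15 and 8 V/SVZ over CP peaks. Channels rose above the range with peaks in the gene body or 5 kb of it (percentile 98.3) and with unmatched random lists (99.97), and cell cycle genes within control peaks (98.2). No Hox gene symbol occurs in the 4 tables used here, and whether this comes from the tissue or from how the tables were made is not known, so that list has no percentile.

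Of the tests on X promoters in CP, those of sequencing depth and of female cells were chosen only after the result was seen. A deeper CP library would place X promoters at the autosomal median log2 tag ratio of 0.86. They stood at 2.43, above random autosomal sets (0.89 to 1.21), so the excess of CP tags was not the same in all classes. But X promoters were singled out by CP over V/SVZ calls on the same tags, and all shared peaks in that list had a median of 1.88. A raised ratio was thus largely built in, and these values are no independent test of depth. Stronger capture of densely methylated DNA in CP would give X promoters the ratio of imprinted and germline promoters: in tags the intervals were apart (2.21 to 2.61 and 1.51 to 1.99), but in tags per bp the X median was 1.58 and the intervals met, since CP peaks are longer, so the choice of measure keeps this open. More female cells in the CP sample, with an inactive X methylated at promoters, could raise X and lower Y: X outside promoters stood at 1.39, but the median of Y and unplaced Y sequence, 0.58, had an interval that includes the autosomal value, so these cannot be told apart. The sex of the embryos is not given in the sources used here, and a tissue difference on X remains untested.

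For imprinted and germline promoters in CP, the tests of depth, of female cells and of capture were all set before their results were seen. Depth would place them at 0.86, whereas Plagl1, Sycp1 and the others had a median of 1.90. Random autosomal sets matched on tags ranged from 0.81 to 1.39. In tags per bp the median of these promoters was 1.49, against an autosomal median of 0.71. However, the pattern tested came from CP over V/SVZ calls on the same tags. All shared peaks in that list had a median log2 tag ratio of 1.88. A raised ratio was thus largely built in, and these values are no independent test of depth. More female cells would remove the germline list once X genes are left out, but it stayed at percentile 99.89. Only 3 of its 21 genes with a peak are on X, so this test could hardly have removed it. It shows only that X genes do not carry the germline result. The imprinted list had 0 genes with a peak on X and was not put to this test. Stronger capture of dense methylated DNA predicts a raised ratio at other autosomal promoters too, and these stood at 1.08 against 0.86, so capture could produce part of this pattern and a tissue difference remains untested.

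For escape from X inactivation, the tests were set before the result was seen: if an inactive X lies behind the promoter peaks, genes such as Kdm5c and Ddx3x that escape silencing would lack them. Of 4 escape genes with a control peak, 0 had a CP over V/SVZ promoter peak, against 1.94 at the share of all X genes (265 of 545). Kdm5c and Ddx3x each had 1 CP over V/SVZ peak that was not counted as a promoter peak. With so few genes, an inactive X and chance cannot be told apart.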
